A study of Sus scrofa with 55 samples.

How the data were processed

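The cytoplasmic RNA of 55 single oocytes was measured with Smart-seq2, a full-length single-cell cDNA protocol, after the genomic DNA of the same cell had been spun off. The oocytes came from 5 antral follicle stages of 4 pubertal Landrace and Yorkshire gilts (Sus scrofa) aged 208 to 210 days. The gilts had received 5 IU of pregnant mare serum gonadotropin, a hormone that promotes follicle growth, 48 h before their ovaries were taken, and the cDNA went through 16 PCR cycles. The animal is the replicate: gilt 201 gave 14 oocytes, gilt 205 gave 9, gilt 801 gave 12 (none at stage 5) and gilt 803 gave 20. The design text speaks of 62 oocytes, of DNA methylation, of somatic cells and of maturation in culture; these other data are not analysed here.

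The deposited count table holds raw counts per Ensembl gene ID, whole numbers with 1 oocyte per column and no normalization. Per the submitters' processing notes, the tools were Trim Galore 0.4.3, HISAT2 2.1.0, featureCounts and StringTie 1.2.2, without roles or order, and the genome build, annotation release and strand setting are not given in the sources used here, so no gene positions are stated. A table of 25880 IDs was read, of which 14857 had a symbol and 11023 had none. A further deposited table is named for TPM, but its columns do not share the sum that such values have; its unit is treated as other, a length-scaled value whose scale per oocyte the authors do not state. That table was used as an alternative measure only, over 23498 genes, since its last line ends after 21 of 55 values and 2382 genes are missing from it.

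Total counts per oocyte ran from 151104 to 38282850, with a median of 12139540. The CPM of 3 counts in an oocyte was taken as the limit for a gene with 0 counts there. No 0 was replaced by that limit in the levels or fits. Shares of counts in single oocytes were given 95% Wilson binomial intervals. These intervals and limits cover counting error only, because PCR copies without molecular identifiers are not independent molecules. Counts were summed over the oocytes of each gilt and stage (19 sums) and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by stage, estimateDisp, glmQLFit and glmQLFTest). The model held stage and gilt, and Benjamini-Hochberg adjusted p under 0.05 was called, two-sided. A total of 15637 genes were tested, 12635 with a symbol, and the common biological coefficient of variation was 1.24. Stage 5 was compared with stage 1, each stage with the one before it, all stages with an F test, and a trend with stage as a number from 1 to 5. Fitted changes are log2 values ± SE; levels are CPM (count shares scaled by TMM) of the sums, as mean ± SD over gilts or stages.

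Gilt was kept in the model because the animals are named in the labels and each gave oocytes of nearly every stage. The pairing was checked by correlating deviations from the stage means: sums of the same gilt had a mean r of 0.0124 (gilt 201), 0.136 (gilt 205), 0.141 (gilt 801) and 0.133 (gilt 803), against -0.0318 for sums of different gilts. The comparisons of each gilt with the mean of the others, and the F test among gilts, used the same model; they were added after gilt 803 was seen to differ.

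A set of 26 gene lists was tested with camera in limma 3.58.1 at a preset correlation of 0.01, also with an estimated correlation and with fry, on lists with at least 5 measured genes. The lists cover oocyte-specific and maternal-effect genes; meiotic arrest and resumption; spindle, kinetochore and spindle checkpoint; meiotic cohesin and recombination; maternal mRNA storage and translational control; deadenylation and mRNA decay; cytosolic and mitochondrial ribosomal proteins; nuclear-encoded oxidative phosphorylation; mitochondrially encoded proteins; proteasome; DNA methylation machinery; histone-modifying enzymes; and TGF-beta superfamily signalling. They further cover insulin and mTOR signalling, cholesterol and isoprenoid synthesis, glycolysis and pentose phosphate pathway, fatty acid use and lipid droplets, redox defence, stress response and apoptosis, histones, nuclear pore and lamina, and RNA polymerase II transcription. The last lists hold markers of other cells that a library could contain: granulosa and cumulus cells, theca and stroma, and blood, immune and endothelial cells.

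For genes named in the text, the rule took the 10 largest rises and falls among called genes with a symbol, at least 10 CPM and the same sign in every gilt (4 for neighbouring stages, 5 for the trend), up to 4 members of each list for stage 5 against stage 1, and always GDF9, BMP15, ZP3, CCNB1, MOS, DNMT1 and DNMT3A. Other genes in the text were chosen after their values were seen. The stage comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

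For each oocyte, the log10 total, the genes detected at an equal depth of 1109755 counts, the mitochondrially encoded percent and the granulosa and cumulus CPM (log2 with a pseudocount of 1) were averaged per gilt and stage. Their slopes over stages, within gilts, were tested with 100000 permutations of stage labels within gilts, two-sided (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). At equal depth 3 oocytes were too shallow and left out. The mitochondrially encoded percent covers only the 13 genes of the list of mitochondrially encoded proteins. Mitochondrial rRNA and tRNA are not counted in it, and the alternative without mitochondrially encoded genes removed only these 13.

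Alternatives were DESeq2's size factors, no filter, a stricter filter (10 CPM in 4 sums), DESeq2 1.42.0, a model without gilt, each oocyte as a library, limma on log2 CPM or on the length-scaled table (pseudocounts 1 and 0.1, with and without a minimum of 1, or rescaled), sums of at least 2 oocytes, and each gilt left out. Counts were also tested without mitochondrially encoded genes and without the 13 libraries in which granulosa and cumulus markers held more counts than oocyte genes; these and the rescaled table were added after the data were seen.

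The tests were tried on simulated data with 50 genes changed at each of 4 sizes between stage 5 and stage 1. At changes of 4, 16, 64 and 256-fold edgeR recovered 2%, 38%, 78% and 96% with 0 false calls; DESeq2 recovered 8%, 58%, 98% and 100% with 180 false calls, and limma 0%, 22%, 52% and 68% with 0. A list of 30 genes raised 4-fold gave a camera p of 1.02e-15 (3.62e-06 with an estimated correlation), and 3 of 100 unchanged lists had a p under 0.05. That share is not a false-call rate for the measured lists. Between stage 5 and stage 1 their estimated correlation reached 0.66 for cytosolic ribosomal proteins and 0.96 for mitochondrially encoded proteins. When the sums of these stages were divided in other ways, 33 of the other divisions also called lists. The permutation test of slopes gave a p under 0.05 in 11 of 200 simulations without a slope and 45 of 50 with a slope of 0.5 SD per stage.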

Results

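Transcript counts were obtained for 55 single pig oocytes, 11 at antral follicle stage 1, 12 at stage 2, 11 at stage 3, 11 at stage 4 and 10 at stage 5. The median total per oocyte was 7329800 counts at stage 1, 11519013 at stage 2, 13661687 at stage 3, 12998378 at stage 4 and 12929388 at stage 5. The 3 shallowest oocytes, all of gilt 803, could not be brought to the common depth of 1109755 counts. At that depth an oocyte had 8225 ± 2173 genes with at least 1 count (SD, n = 19 gilt-by-stage means).

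The oocytes carried large amounts of mitochondrial and zona pellucida RNA. COX1, a mitochondrially encoded subunit of cytochrome c oxidase, was the most abundant transcript with a mean of 152881 CPM over all oocytes. ZP3, a glycoprotein of the egg coat, averaged 5735 CPM, DNMT1, the maintenance DNA methyltransferase, 2685 CPM and GDF9, an oocyte-secreted growth factor, 1189 CPM. The mitochondrially encoded share of counts, that of the 13 listed protein genes without mitochondrial rRNA, varied widely. It ranged from 2.104% (95% Wilson interval 2.09 to 2.11) in stage 2 gilt 803 oocyte 2 to 91.8% (interval 91.79 to 91.81) in stage 1 gilt 801 oocyte 1. In 13 oocytes that share was under 10%, in 12 it lay between 10 and 60%, and in 30 it was 60% or more. Granulosa and cumulus markers held more counts than the oocyte genes in 13 libraries, 12 of the 20 of gilt 803 and 1 of the 12 of gilt 801. These libraries fell at every stage, 3 at stage 1, 1 at stage 2, 3 at stage 3, 4 at stage 4 and 2 at stage 5.

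**Figure D1:**
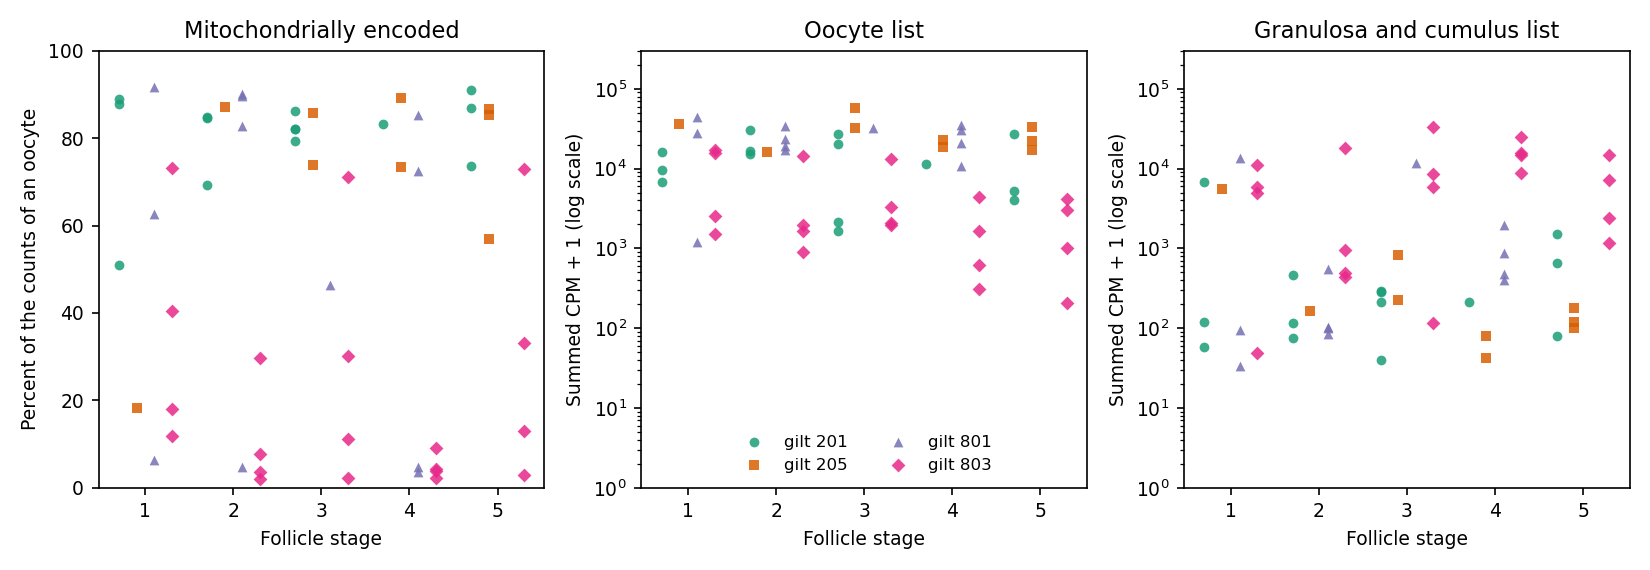
Each point is 1 of 55 oocytes, by follicle stage and coloured by gilt, with the mitochondrially encoded percent of its counts and the summed CPM of the oocyte list and of the granulosa and cumulus list (log axes, with a pseudocount of 1). Oocytes of gilt 803 had the lowest mean mitochondrially encoded share (22.2%, against 52.1% in gilt 801, 68.6% in gilt 205 and 81.0% in gilt 201). They had the highest mean granulosa and cumulus level (8950 CPM, against 4322 in gilt 801, 1296 in gilt 205 and 737 in gilt 201).

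None of the 4 library measures followed the stages within gilts. The mitochondrially encoded share had a slope of 2.42 ± 2.91 percent per stage (SE, 19 gilt-by-stage means, permutation p = 0.474), and without gilt 205 the slope was -1.03. The granulosa and cumulus level had a slope of -0.0327 ± 0.341 log2 units per stage (permutation p = 0.922), which became 0.450 without gilt 205 and 0.127 with medians over oocytes in place of means. Genes detected at equal depth had a slope of -316 ± 331 per stage (permutation p = 0.377), and without gilt 205 it was -51.3. The log10 total had a slope of 0.0868 ± 0.0456 per stage (permutation p = 0.0972), and without gilt 205 it was 0.133 (permutation p = 0.0266), while without gilt 803 it was 0.00415 (permutation p = 0.783). Stage 1 had the highest theca and stroma marker level, 1365 ± 710 CPM (SD, n = 4 gilts), against 291 ± 321 CPM at stage 5 (n = 3). Without stage 1 gilt 201 oocyte 1, at 6045 CPM, the stage 1 mean was 876, and the medians over oocytes were 158 and 41.6.

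The comparison of stage 5 with stage 1 asks how the oocyte's transcripts differ between the latest and the earliest antral stage. No single gene passed the test, and 5 gene lists were called by camera at its preset correlation but 0 with an estimated correlation. Cholesterol and isoprenoid synthesis genes were lower at stage 5 by camera: 21 of 26 measured members were below stage 1, with a median log2 change of -1.27 (adjusted p = 0.00101; adjusted p = 0.432 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 42 of 43 members, with a median of -0.81 (adjusted p = 0.00102; adjusted p = 0.646 with an estimated correlation). Genes of the spindle, kinetochore and spindle checkpoint were higher, 22 of 31 with a positive change and a median of 0.69 (adjusted p = 0.00109; adjusted p = 0.432 with an estimated correlation).

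HMGCS1, which makes the HMG-CoA of the sterol pathway, had 30.9 ± 37.9 CPM at stage 1 (SD, n = 4 gilts) and 2.25 ± 3.47 at stage 5 (n = 3), a fitted change of -2.77 ± 1.28. CYP51A1, the lanosterol demethylase, had a change of -3.10 ± 1.45, ACAT2 of -3.16 ± 1.56 and INSIG1, a sterol-regulated brake on the pathway, of -2.58 ± 1.33. This list's call ended without gilt 803, at an adjusted p of 0.234; without the 13 granulosa-rich libraries its adjusted p was 3.77e-05. Among ribosomal proteins, RPSA had a change of -1.63 ± 0.786, RACK1 of -1.38 ± 0.762, RPL4 of -1.38 ± 0.776 and RPS4X of -1.26 ± 0.706. Without gilt 205 the ribosomal call ended (adjusted p = 0.581), as it did without gilt in the model (adjusted p = 0.381). For the spindle, TTK, a checkpoint kinase also called MPS1, had 10.3 ± 5.91 CPM at stage 1 and 25.0 ± 8.72 at stage 5, a change of 1.52 ± 0.928. PRC1, which bundles midzone microtubules, had a change of 1.17 ± 0.723, TPX2, a spindle assembly factor, of 1.17 ± 0.811 and SPC25, a kinetochore subunit, of 2.50 ± 1.80. The spindle call held without each gilt in turn, at adjusted p from 0.000216 to 0.0337.

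Genes of TGF-beta superfamily signalling were higher as a list, with 21 of 34 positive and a median of 0.42 (camera adjusted p = 0.0341; adjusted p = 0.432 with an estimated correlation). BMP4, a ligand, had a change of 3.28 ± 1.73, SMAD3, a signal transducer, of 2.35 ± 1.52 and SMAD9 of -5.93 ± 2.55. The call ended without gilt 201 (adjusted p = 0.0935), without gilt 205 (0.149) and without mitochondrially encoded genes (0.0501). Theca and stroma markers were lower, 13 of 17 negative with a median of -2.60 (adjusted p = 0.00128; adjusted p = 0.432 with an estimated correlation). CYP17A1, the androgen-making enzyme of theca cells, was the 1 member lower when adjusted over the list alone, against 0 over all genes, at -8.95 ± 2.41. COL3A1, a fibrillar collagen of stroma, had a change of -6.40 ± 2.37, COL1A1 of -4.05 ± 1.74 and DCN of -3.73 ± 1.72. That call ended without gilt 201 (adjusted p = 0.0710), without gilt 205 (0.149) and without gilt in the model (0.0842). No other list had a member past the threshold when adjusted over the list alone, and fry called 0 lists.

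Oocyte-specific and maternal-effect genes were not called (18 measured, median -0.83, 13 negative, adjusted p = 0.569). ZP3 went from a mean of 6882 ± 2170 CPM at stage 1 to 8927 ± 7593 at stage 5, while its fitted change, which weighs gilts on the log scale, was -2.43 ± 1.19. For GDF9 the means were 1060.0 ± 632 and 1381 ± 1162 CPM and the fitted change -1.45 ± 0.948, again with opposite signs. The stage 5 means hold no oocyte of gilt 801. TMM-scaled ZP3 and GDF9 rose from stage 1 to stage 5 in gilts 201 and 205 and fell in gilt 803. Their negative fitted changes thus rest on gilt 803, which held both granulosa-rich libraries of stage 5. Before scaling, ZP3 ran from 250 to 7435 CPM over the stage 1 oocytes of gilt 803 and from 2.14 to 1613 over those of stage 5. BMP15, the partner of GDF9, had a fitted change of 0.94 ± 1.02. CCNB1, the cyclin of the maturation-promoting factor, had 72.2 ± 11.7 CPM at stage 1 and 137 ± 79.4 at stage 5, a change of 1.18 ± 0.734. MOS, the kinase upstream of MAP kinase in meiosis, had a change of -0.09 ± 0.816. DNMT1 had a change of 1.08 ± 0.852 and DNMT3A, a de novo DNA methyltransferase, went from 46.0 ± 14.2 to 133 ± 125 CPM, a change of 1.62 ± 0.789.

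**Figure D2:**
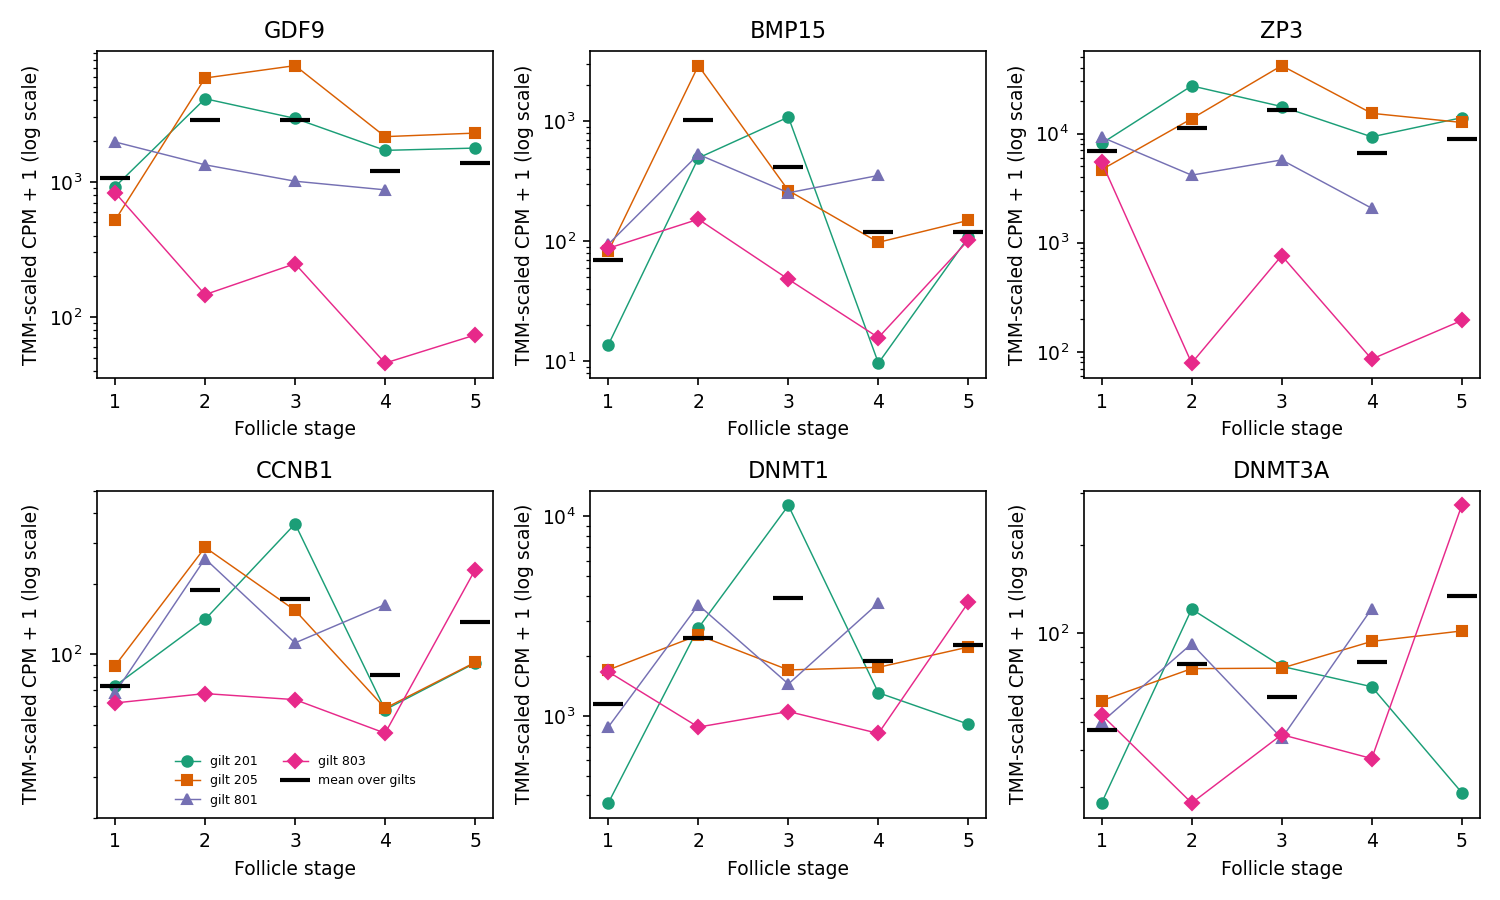
Level (TMM-scaled CPM with a pseudocount of 1, log axis) of GDF9, BMP15, ZP3, CCNB1, DNMT1 and DNMT3A against follicle stage, with 1 point per gilt joined by a line (n = 4, and 3 at stage 5) and a black bar at the mean over gilts. The gilts lay far apart within stages, as for ZP3, whose SD at stage 3 (18340.0 CPM) exceeded its mean there (16500.0 CPM).

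The remaining lists were not called between stage 5 and stage 1. Adjusted p was 0.0831 for the DNA methylation machinery (median 0.25), 0.0864 for histone-modifying enzymes (0.23), 0.102 for deadenylation and mRNA decay (0.33), 0.215 for nuclear pore and lamina (0.21) and 0.215 for RNA polymerase II transcription (0.12). It was 0.289 for nuclear-encoded oxidative phosphorylation (0.06), 0.406 for the proteasome (-0.06), 0.449 for meiotic arrest and resumption (-0.05), 0.569 for maternal mRNA storage (0.01), 0.801 for meiotic cohesin and recombination (-0.26), 0.801 for histones (0.19), 0.935 for mitochondrial ribosomal proteins (-0.26) and 0.986 for insulin and mTOR signalling (-0.06). Lower medians with no call were found for redox defence (-0.42, adjusted p = 0.107), fatty acid use (-0.96, 0.207), stress response (-0.65, 0.318) and glycolysis (-0.51, 0.597). Granulosa and cumulus markers had a median of -0.73 (0.102) and blood, immune and endothelial markers of -2.30 (0.0831). The mitochondrially encoded list had a median of -0.77 with 13 of 13 negative, while camera gave its direction as up (adjusted p = 0.266). These members moved almost as 1, with an estimated correlation of 0.96. Their unscaled share of counts went the other way, from 45.9 ± 24.7% at stage 1 (SD, n = 4 gilts) to 63.6 ± 28.8% at stage 5 (n = 3). The sign thus depends on the TMM factors of the sums, which ran from 0.270 to 3.59. Signs also differed between median, mean and test for meiotic arrest, cohesin, mRNA storage, mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, DNA methylation, insulin and mTOR signalling, and histones. The median change of all genes was -0.27. With 1 gilt left out, calls arose for mRNA decay (adjusted p = 0.0337), histone-modifying enzymes (0.0337), redox defence (0.00584) and granulosa markers (0.0107) without gilt 201, and for oxidative phosphorylation (0.000111) and the proteasome (0.0257) without gilt 205. Calls arose for mitochondrially encoded proteins (0.0129) and DNA methylation (0.0163) without gilt 801, and for mitochondrially encoded proteins (0.000756), granulosa markers (0.000756) and blood, immune and endothelial markers (0.0355) without gilt 803. Without gilt in the model they arose for mitochondrially encoded proteins (0.0197), DNA methylation (0.0351) and histone-modifying enzymes (0.0351).

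At the level of single genes edgeR called 0 of 15637 between stage 5 and stage 1, with 840 at an unadjusted p under 0.05 and 782 expected by chance. DESeq2 called 368 (355 lower), the tool that made 180 false calls on simulated data, and limma 0. Without a low-count filter edgeR called 23, and without gilt 201 it called 1. The median SE was 1.76 log2 units, or 1.09 for genes of at least 10 CPM. On simulated data edgeR recovered 2% of genes changed 4-fold and 38% of those changed 16-fold, so most changes up to that size in single genes would be missed here.

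Comparisons of each stage with the one before it ask where along the series the oocyte's transcripts change. From stage 1 to stage 2, ACSBG1, an acyl-CoA synthetase, had the smallest p with a change of -7.31 ± 1.58 (adjusted p = 0.692), and COX4I2, an isoform of a cytochrome c oxidase subunit, had -8.11 ± 1.90. Both went the other way from stage 2 to stage 3, at 8.27 ± 1.65 (adjusted p = 0.257) for ACSBG1 and 10.80 ± 1.99 (adjusted p = 0.165) for COX4I2, which share the stage 2 libraries. IHH, a hedgehog ligand on the granulosa list, had -12.85 ± 2.94 from stage 1 to stage 2, where the granulosa and cumulus markers went from 4471 ± 1522 to 1383 ± 2371 CPM (SD, n = 4). Mean levels of BMP15 were 68.4 ± 37.4, 1015 ± 1263, 410 ± 456, 118 ± 161 and 119 ± 25.6 CPM at stages 1 to 5, and those of DNMT1 were 1151 ± 646, 2442 ± 1139, 3882 ± 4978, 1886 ± 1253 and 2276 ± 1402 CPM. From stage 3 to stage 4, PDK4, an inhibitor of pyruvate dehydrogenase, had -5.67 ± 1.36, and from stage 4 to stage 5, E2F7, a repressor of cell cycle genes, had 7.04 ± 1.86; neither passed.

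For stage 2 against stage 1 edgeR called 0 genes (1034 at unadjusted p under 0.05), DESeq2 415, limma 0, and edgeR without a filter 111. Leaving out gilt 803 gave 50 calls there, 49 of them lower at stage 2. For stage 3 against stage 2 edgeR called 0 (728 unadjusted), DESeq2 311, limma 0, edgeR without a filter 29, edgeR without gilt 803 called 7, and with each oocyte as a library 3. For stage 4 against stage 3 the counts were 0 (646 unadjusted), 267 by DESeq2, 0 by limma and 14 without a filter. For stage 5 against stage 4 they were 0 (466 unadjusted), 216 by DESeq2, 0 by limma, 4 without a filter and 1 without gilt 201. Across all stages the F test called 0 (840 unadjusted), with 47 by DESeq2, 0 by limma, 216 without a filter, 34 with oocytes as libraries, 45 without gilt 803 and 1 without gilt 201.

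The trend asks which transcripts rise or fall steadily over the 5 stages. C1QA, a chain of complement C1q made by macrophages, fell by 2.90 ± 0.504 log2 units per stage (adjusted p = 0.0396), with a negative slope in all 4 gilts. In gilts 205 and 801 that slope rested on 1 stage 1 library each. These had 2.27 CPM in gilt 205 and 0.42 CPM, the level of 3 counts, in gilt 801. Its level was 9.07 ± 10.9 CPM at stage 1, 24.7 ± 49.4 at stage 2, 3.09 ± 5.53 at stage 3, 0 at stage 4 (n = 4 each) and 0.00462 ± 0.00801 at stage 5 (n = 3). Of the 4485 C1QA counts at stages 1 to 3, 60.5% came from 1 library, stage 2 gilt 803 oocyte 3. ZDBF2, an imprinted gene in mammals, fell by 2.14 ± 0.376 per stage (adjusted p = 0.0396) with a mean of 0.309 CPM over all oocytes, near the detection limit. Both slopes rest on stages without counts, and their size depends on the prior count of the fit. Both calls ended with any 1 gilt left out, at adjusted p from 0.0925 to 0.594.

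Cytosolic ribosomal protein genes fell over the stages as a list, with 43 of 43 slopes negative and a median of -0.20 per stage (camera adjusted p = 1.49e-05; adjusted p = 0.614 with an estimated correlation). Cholesterol and isoprenoid synthesis fell, 23 of 26 negative, median -0.26 (adjusted p = 0.00110; 0.374 with an estimated correlation). Theca and stroma markers fell, 14 of 17 negative, median -0.60 (adjusted p = 0.00110; adjusted p = 0.374 with an estimated correlation), with CYP17A1 the 1 member lower when adjusted over the list alone. Blood, immune and endothelial markers fell, 14 of 18 negative, median -0.80 (adjusted p = 0.00966; adjusted p = 0.374 with an estimated correlation). CD163, a scavenger receptor of macrophages (-2.53 ± 0.605), and NKG7, a granule protein of cytotoxic lymphocytes (-2.39 ± 0.647), were the 2 members lower when adjusted over the list alone, and 0 passed over all genes. INSR, the insulin receptor, was the 1 member of its list lower when adjusted over the list alone (-1.87 ± 0.473 per stage), from 16.5 ± 11.6 CPM at stage 1 to 0.0392 ± 0.0356 at stage 5, while the list of insulin and mTOR signalling was not called (adjusted p = 0.916).

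Spindle genes rose as a list, 20 of 31 positive with a median of 0.06 per stage (adjusted p = 0.0168; adjusted p = 0.424 with an estimated correlation). TGF-beta superfamily genes rose, 23 of 34 positive, median 0.11 (adjusted p = 0.0168; adjusted p = 0.374 with an estimated correlation). Deadenylation and mRNA decay genes, which remove maternal messages, rose, 22 of 35 positive, median 0.06 (adjusted p = 0.0487; adjusted p = 0.374 with an estimated correlation). From stage 1 to stage 5 PARN, a poly(A) ribonuclease, had a change of 2.28 ± 1.08 and CNOT6L, a deadenylase of the CCR4-NOT complex, of 1.65 ± 0.807. The other 19 lists had adjusted p from 0.0755 to 0.990, and fry called 0 lists. Among them, median, mean and test differed in sign for meiotic arrest, mRNA storage, oxidative phosphorylation, proteasome, DNA methylation, insulin and mTOR signalling, and histones.

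**Figure D3:**
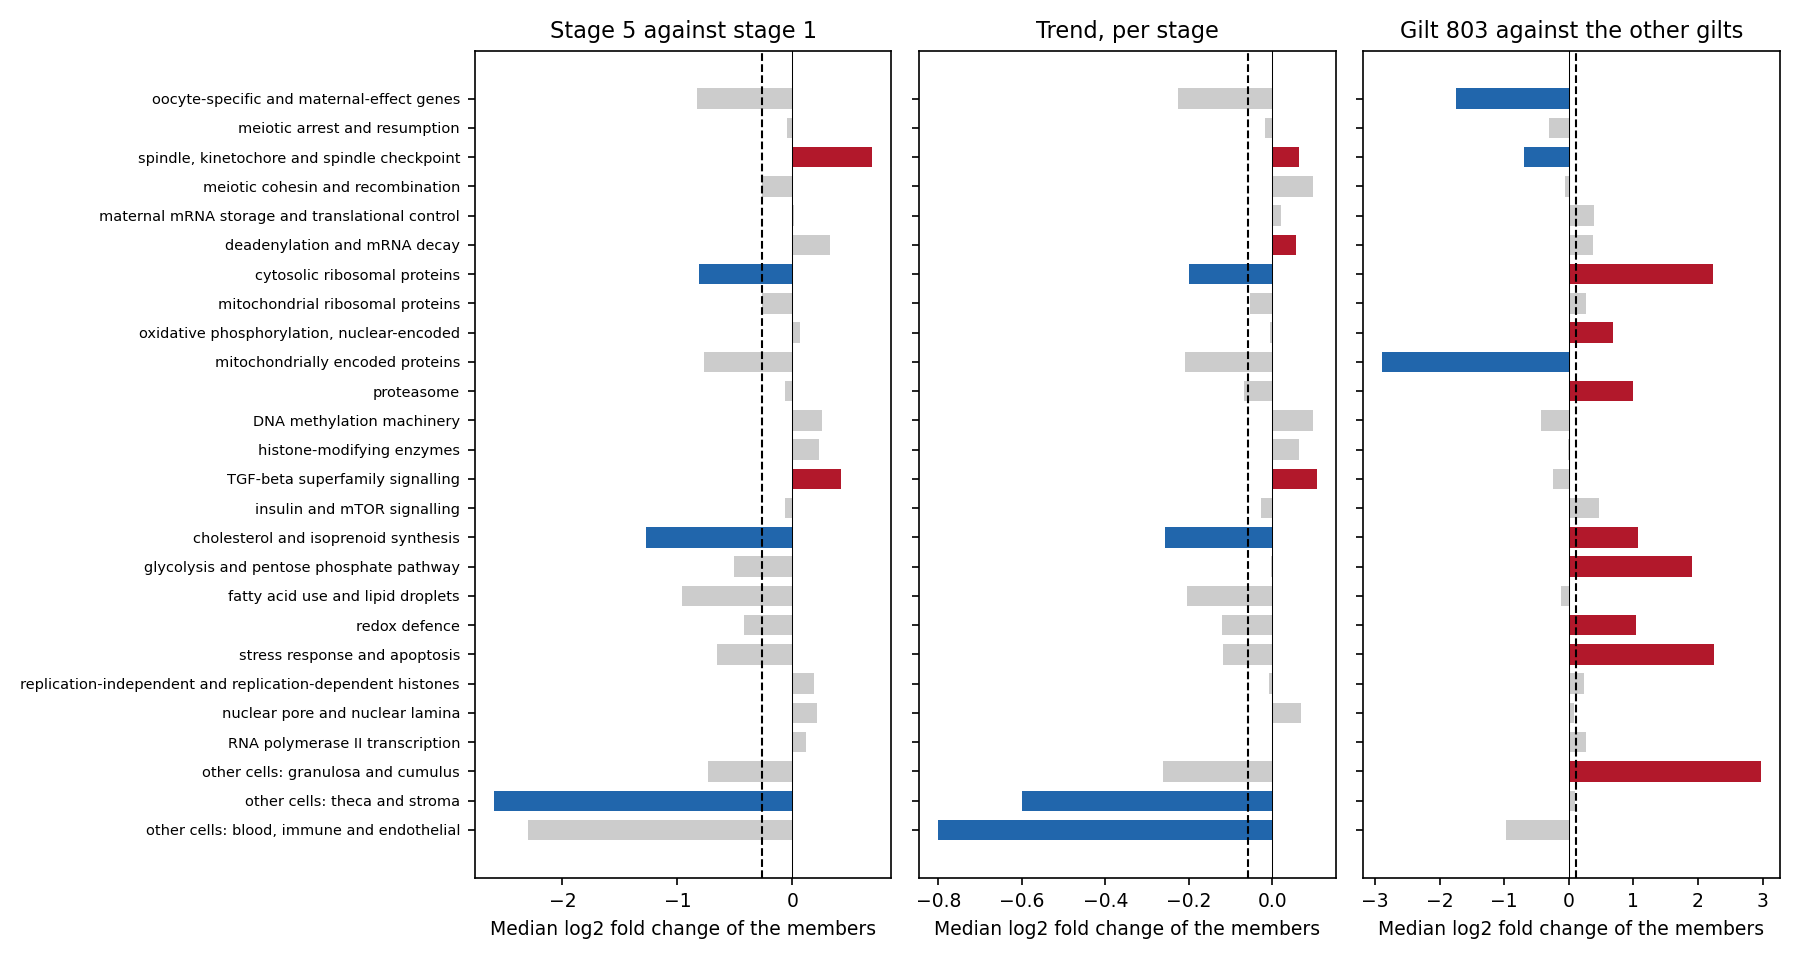
Bars give the median fitted log2 change of the measured members of each of 26 gene lists for stage 5 against stage 1, for the trend per stage and for gilt 803 against the other gilts, coloured where camera's adjusted p was under 0.05 (red up, blue down) and grey elsewhere; the dashed line is the median of all genes. Cytosolic ribosomal proteins had a median of -0.81 between the stages and of 2.24 between the gilts.

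Each of the 7 list calls of the trend ended when some 1 gilt was left out. Without gilt 205 the calls of ribosomal proteins (adjusted p = 0.180), TGF-beta signalling (0.186) and mRNA decay (0.249) ended. Without gilt 803 those of cholesterol synthesis (0.144), blood, immune and endothelial markers (0.0592), the spindle (0.0850) and mRNA decay (0.0935) ended. In all 4 lists were called without gilt 803, the newly called granulosa markers among them. Without gilt 201 the theca (0.109) and spindle (0.0652) calls ended, and without gilt 801 that of mRNA decay (0.0666). New calls arose without gilt 201 for histone-modifying enzymes (0.0151), redox defence (0.0389), nuclear pore (0.0364) and granulosa markers (0.0329), without gilt 205 for oxidative phosphorylation (3.17e-05), mitochondrially encoded proteins (0.0173) and mitochondrial ribosomal proteins, then up (0.0472), and without gilt 803 for granulosa markers (0.000762). Without gilt in the model 2 lists were called. Without the 13 granulosa-rich libraries 14 lists were called, among them nuclear-encoded oxidative phosphorylation, then down (adjusted p = 0.000459). For single genes edgeR called 2 (900 at unadjusted p under 0.05), DESeq2 161 and limma 0. Leaving out gilt 803 gave 2 other genes, and leaving out gilt 201, 205 or 801 gave 0, as did a stricter filter, a model without gilt, and the removal of the granulosa-rich libraries.

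With all 4 gilts in the model, more genes differed among gilts than among stages. The F test among the 4 animals called 339 genes in edgeR (1976 at unadjusted p under 0.05), 1006 in DESeq2 and 225 in limma. Leaving out gilt 803 gave 27, fewer than the F test among stages then called, so the order rests on gilt 803. Leaving out gilt 205 gave 79 and gilt 201 gave 549, and without the 13 granulosa-rich libraries 14 were called. In gilt 201 the unnamed gene ENSSSCG00000035520 was higher than in the other gilts by 9.25 ± 0.784 (adjusted p = 9.25e-08), the 1 gene called there; 14 were called without gilt 205 and 37 without gilt 803. In gilt 801 the same gene was lower, at -8.10 ± 1.23 (adjusted p = 0.00456). The 3 genes higher in gilt 801 were ENSSSCG00000012100 (4.72 ± 0.719), ENSSSCG00000018072 (5.32 ± 0.935) and ENSSSCG00000018079 (4.54 ± 0.814); without gilt 201 none of the 4 was called and 2 other genes were, without gilt 803 there were 3 calls, 2 of them shared, and without gilt 205 there were 13, with all 4 among them. Gilt 205 had 11 genes higher and 7 lower, a balance that turned with the setting (156 and 723 with DESeq2, 46 and 257 with no filter, 18 and 93 without gilt 201, 13 and 57 without gilt 801, 58 and 2 on the length-scaled table with pseudocount 1). Lower there were TNFRSF12A, a TNF receptor family member (-4.57 ± 0.803), ANXA5, a phospholipid-binding annexin (-3.23 ± 0.661), SLC25A3, the mitochondrial phosphate carrier (-3.15 ± 0.623) and the ribosomal protein gene RPS29 (-2.79 ± 0.569). The 18 calls became 111 without gilt 201, 70 without gilt 801 and 3 without gilt 803, none of them these 4 (adjusted p from 0.265 to 0.371).

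Gilt 803 stood apart, with 688 genes higher and 44 lower than in the other gilts. On the length-scaled table most calls were lower instead (28 higher and 44 lower with pseudocount 1, 14 and 79 with 0.1, 9 and 38 with no filter), except when that table was rescaled (543 and 30). The genes of the egg coat were lower: ZP2 by -4.64 ± 1.14, at 442 ± 795 CPM (SD, n = 5 stages) against 4512 ± 1631 in gilt 201, ZP4 by -4.41 ± 0.982, ZP3 by -4.30 ± 0.968, and GDF9 by -3.38 ± 0.743. In total, 5 of 18 oocyte-specific genes were lower (11 when adjusted over the list alone), and the list fell (median -1.75, camera adjusted p = 5.37e-11; adjusted p = 0.0722 with an estimated correlation). Granulosa and cumulus markers were higher, 9 of 27 (15 when adjusted over the list alone, with 2 lower; median 2.97, adjusted p = 1.58e-09; adjusted p = 0.0722 with an estimated correlation). They included HAS2, a hyaluronan synthase of expanding cumulus (8.22 ± 1.25), CYP11A1, the first enzyme of steroid synthesis (5.80 ± 1.01), the gap junction gene GJA1 (5.22 ± 0.775, 536 ± 340 CPM against 41.7 ± 50.2 in gilt 201) and SERPINE2 (4.00 ± 0.811). Mitochondrially encoded genes were lower, 6 of 13 (13 when adjusted over the list alone), such as ND1 (-3.30 ± 0.903) and ATP8 (-5.16 ± 1.02). The list had a median of -2.89 (camera adjusted p = 1.50e-16, and adjusted p = 0.0974 with an estimated correlation). The fall of ATP8 was not particular to gilt 803. Scaled to mitochondrially encoded counts, its median was 507 in gilt 201 and 1275 in gilt 803. It was 13951 in gilt 205 and 13548 in gilt 801.

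Cytosolic ribosomal proteins were higher in gilt 803 in 38 of 43 (40 when adjusted over the list alone; median 2.24, adjusted p = 5.25e-37; adjusted p = 0.0722 with an estimated correlation), as RPS3A (3.06) and RPS12 (2.68). In these same libraries the mean granulosa and cumulus level was 8950 ± 4841 CPM (SD, n = 5 stages). It was 737 ± 906 in gilt 201 and 1296 ± 2412 in gilt 205 (n = 5 each), and 4322 ± 5229 in gilt 801 (n = 4). Glycolytic genes were higher in 9 of 24 (14 over the list alone; adjusted p = 3.04e-11; 0.0722 with an estimated correlation), among them the enzymes PKM (3.93), ALDOA (3.86) and ENO1 (3.66, 4795 ± 3127 CPM against 668 ± 660 in gilt 201). Stress response genes were higher in 8 of 28 (14 over the list alone; adjusted p = 2.34e-08; 0.0544 with an estimated correlation), as GADD45B (6.10), the cell cycle inhibitor CDKN1A (4.65) and the early response gene EGR1 (3.68). Cholesterol synthesis genes were higher in 9 of 26 (11 over the list alone; adjusted p = 1.05e-05; 0.0722 with an estimated correlation), as ACAT2 (4.76), CYP51A1 (4.57), DHCR7 (3.22) and IDI1 (2.101). Redox genes were higher in 6 and lower in 1 of 27 (9 and 1 over the list alone; adjusted p = 0.000184; 0.293 with an estimated correlation), as HMOX1, heme oxygenase (7.19), NQO1 (5.47) and GPX3 (4.10). The proteasome (adjusted p = 0.000179; 0.293 with an estimated correlation) and nuclear-encoded oxidative phosphorylation (0.00105; 0.739) were higher and the spindle (0.00137; 0.293) lower as lists, each with 0 members called.

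The 15 other lists were not called, with adjusted p from 0.110 to 0.970, and median, mean and test differed in sign for meiotic arrest, DNA methylation, histone-modifying enzymes, TGF-beta signalling, fatty acid use, nuclear pore, and blood, immune and endothelial markers. Among the largest rises by the rule were SLC38A4, an amino acid transporter (11.82 ± 1.497), TMEM100 (10.64 ± 1.48), FABP4, a fatty acid carrier (9.39 ± 1.64), RETREG1, a receptor for turnover of the endoplasmic reticulum (9.06 ± 0.936), HAS2, SOCS3 (8.15), NR4A1 (8.15), RELL1 (8.03) and PRKCB (7.54). The largest falls were ATP8, DPEP1 (-4.66), ZP2, ZP4, DND1, an RNA-binding germ cell protein (-4.31), ZP3, CNBD2 (-4.00), NFIB (-3.53), NAALAD2 (-3.50) and COCH (-3.46). Of these, ATP8 was low in gilt 201 too when scaled to mitochondrially encoded counts.

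For gilt 803 edgeR called 732 genes (2705 at unadjusted p under 0.05), DESeq2 2492 and limma 353. Without the 13 granulosa-rich libraries, 12 of them of this gilt, 5 genes were called; without gilt 205 there were 120 and without gilt 801 there were 433. Without those libraries the lists of oocyte genes and mitochondrially encoded proteins were still down and ribosomal proteins still up, at adjusted p of 8.06e-05, 6.72e-07 and 0.00174. Granulosa and cumulus markers (0.828) were no longer called, but the libraries had been removed by those same markers. Glycolysis (0.828), cholesterol synthesis (0.937), stress response (0.135), redox defence (0.937), the proteasome (0.288) and the spindle (0.937) were no longer called either. Oxidative phosphorylation was then down (8.06e-05). Without gilt 205 the call of oxidative phosphorylation ended (0.0666) and one for mRNA decay arose (0.0305).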

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

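The tests of depth and of RNA from other cells, and the splits for single genes of stage 5 against stage 1, 2 against 1, 3 against 2 and 4 against 3, were chosen only after the results were seen. The other splits were chosen before theirs were seen, though the comparisons of gilts were themselves added after gilt 803 was seen to differ.

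In 52 groups of 4 to 10 values, each made of the gilts or oocytes of a stage, a sample far from the others was looked for. With normally distributed values chance flags about 1 in 20 groups. The values were taken without logs, and skewed values such as CPM can be flagged more often by chance. The granulosa and cumulus level was far above the other gilts in gilt 803 at stage 2 (4939 CPM, next 219.5) and stage 4 (16038 CPM, next 924), and above the other oocytes of stage 5 in gilt 803 oocyte 2 (14823 CPM, next 7193). C1QA was far above in gilt 803 at stage 2 (98.81 CPM, next 0) and stage 3 (11.35 CPM, next 0.999), and MOS far below there at stage 2 (86.05 CPM, next 505). BMP15 lay far below in gilt 201 at stage 1 (12.71 CPM, next 81.3) and far above in gilt 205 at stage 2 (2892 CPM, next 526.5, from 1 oocyte). CCNB1 was far above in gilt 801 at stage 4 (162 CPM, next 57.8) and DNMT1 in gilt 201 at stage 3 (11340.0 CPM, next 1698).

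C1QA and the blood, immune and endothelial list were lower at later stages. Lower depth at later stages is argued against, since the totals of stages 4 and 5 would give 3464 C1QA counts at the level of stages 1 to 3 and held 1. RNA of other cells in single libraries may account for the fall. Of the 18 tested list members, 7 peaked in the library with the most C1QA, stage 2 gilt 803 oocyte 3. An equal chance for each library would give 0.33, but that value takes the members as independent and the libraries as alike, so it is a weak baseline. That library held 60.5% of the C1QA counts of stages 1 to 3. There NKG7 had 949 CPM, CD68 873 and LYZ 625; none of the 22 members is on another list, and 3 also reached 10 CPM in each of 3 oocyte libraries with few markers of other cells. A difference between stages stays open and untested.

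Gilt 803 differed from the other gilts in 732 genes. Lower depth of its libraries is argued against, since at stage 4, the 1 stage at which they had at least the mean total of the others, 16 of 18 oocyte genes were lower. RNA of granulosa or cumulus cells is a candidate source for the rises. Of the 688 genes higher in gilt 803, 89.4% were higher in the 1 granulosa-rich library of another gilt than in its neighbours. Random genes of the same level gave 71.8% on average and at most 77.3% in 1000 draws. This baseline is weak, since it takes genes as independent and rests on 1 library. The mitochondrially encoded share was 6.26% in that library and 91.8 and 62.7% in its neighbours. Genes that are higher wherever this share is low would pass too. In the 12 granulosa-rich libraries of gilt 803 SERPINE2 had a mean of 4282 CPM, INHA 2924 and CYP11A1 1744. Those libraries were picked by the list that holds these genes, so the levels add no separate evidence. Of the 29 list members 0 are on another list. Of them 7 also reached 10 CPM in each of the 3 oocyte libraries with few such markers. Without the granulosa-rich libraries 5 genes were called, but those libraries were 12 of the 20 of gilt 803 and all of its stage 4. Fewer calls could follow from the loss of samples alone. Then 40 of the named genes kept direction but were no longer called, and 11 kept direction and side of the threshold. Another 5 turned direction, and 2 more did so without a call in either fit. A difference of the animal itself stays open and untested.

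The mitochondrially encoded share of counts lay between 2 and 92% and was under 10% in 13 libraries. Lower depth is argued against, since 7 of the 13 had totals above the median. For 3 of them RNA of other cells is argued against as well: the oocyte list held at least 10 times the counts of the 3 other-cell lists, with totals of 20923950 to 38282850 and 16203 to 17106 genes. In the other 10, RNA of other cells may lower the share, since granulosa and cumulus markers exceeded the oocyte genes in 8. Stage 2 gilt 803 oocyte 1 was not among those 8 and fell just short of the cut of 10 times. Its share was 3.71%, with 14565 CPM of oocyte genes. The granulosa, theca and blood lists had 949, 90.1 and 491 CPM there. All 3 libraries of the first kind came from gilt 801, at stages 2 and 4, and a difference of gilt or stage stays open and untested.

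The gilt-by-stage sums were also split in other ways, in all 35 ways between a pair of stages and in 50 drawn ways elsewhere, the real split included, so that the smallest share there is 1 of 50. No allowance was made for the number of comparisons. Where 0 genes were called every split gives as many, so the splits decide nothing there: 35 of 35 for stage 5 against stage 1 (highest other 12). Chance cannot be excluded for its 5 called lists, matched in 22 of 35 splits (highest other 16). Of the 8 splits that part 3 gilts as the real one does, the real one included, 6 called as many lists, at most 11, and the highest gene count was 0; the split with 12 genes parts 1 gilt and leaves the others wholly on 1 side. For 2 against 1, 3 against 2, 4 against 3 and 5 against 4, with 0 genes called, the count was likewise 35 of 35 by construction, and the highest others were 0, 24, 0 and 1. The 24 came from a split that parts 2 gilts, while the 8 that part 4 gilts gave 0. For any stage, also with 0 genes, it was 50 of 50 (highest other 3).

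For the 2 genes of the trend the share was under 1 in 20 (2 of 50 splits gave as many, the real one included), but 1 drawn split called 9. Chance cannot be excluded for the 7 lists (20 of 50 splits, highest other 16). A split that calls several times the real count, as that with 9, points to a structure of the samples, which was not identified here.

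Among gilts no other split called as many as the real one for the 339 genes (1 of 50 splits, highest other 7). The same held for the 1 gene of gilt 201 (1 of 50, highest other 0) and the 732 of gilt 803 (1 of 50, highest other 231). A share of 1 of 50 is the smallest that these splits can give. Chance is made less likely but is not excluded, since these comparisons were added after gilt 803 was seen to differ. For the 18 of gilt 205 (2 of 50, highest other 19) and the 4 of gilt 801 (2 of 50, highest other 118) the share was under 1 in 20, but 1 drawn split called more than the real one in each. The 118 calls of 1 split for gilt 801 point to a structure of the samples in the same way, again not identified. For the 11 lists of gilt 803 chance cannot be excluded (8 of 50 splits, highest other 13).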

How the results depend on the processing

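The alternatives without mitochondrially encoded genes, without the granulosa-rich libraries and on the rescaled table, and all alternatives of the gilt comparisons, were chosen after seeing the data. Changes of sign within an uncalled result were not tested. With single-gene SEs of 1.76 log2 units between stage 5 and stage 1, depth and spread allowed only large changes to be seen. Where a gene was filtered out or a gilt's own comparison was left without that gilt, and for the gilt comparisons without gilt in the model, no value could be had.

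In the stage comparisons (5 against 1, 2 against 1, 3 against 2, 4 against 3, 5 against 4 and any stage), where edgeR called 0 genes in each, the counts were 23, 111, 29, 14, 4 and 216 without a filter, which tests more genes of low count, and 368, 415, 311, 267, 216 and 47 with DESeq2. With each oocyte as a library they were 3 for stage 3 against stage 2 and 34 for any stage. With 1 gilt left out they ranged from 0 to 1, 0 to 50, 0 to 7, 0 to 0, 0 to 1 and 0 to 45. The trend, with 2 genes, gave 161 with DESeq2, 2 with no filter (1 of them shared) and 0 under a stricter filter, each oocyte as a library, limma on CPM, limma on the length-scaled table (pseudocount 1, pseudocount 0.1, no filter and rescaled), sums of at least 2 oocytes, without mitochondrially encoded genes and without granulosa-rich libraries, and from 0 to 2 with 1 gilt left out, where the 2 without gilt 803 were other genes. The model without gilt is given below; all other alternatives of these comparisons kept their counts, and the cause was not tested.

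The block by gilt mattered for the trend: with no replicate block 0 genes and 2 lists were called, against 2 and 7 with it; elsewhere the counts of calls stayed within 1.5 times. In the log10 totals the slope without the pairing by gilt was 0.0760, against 0.0868.

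Among gilts (339 genes) the counts were 935 without a filter, 184 under a stricter one, 1006 with DESeq2, 873 with each oocyte as a library, 225 with limma on CPM, 106 and 53 on the length-scaled table with pseudocount 1 and no filter, 164 with sums of at least 2 oocytes, 14 without granulosa-rich libraries and 27 to 549 with 1 gilt left out. Gilt 201 (1 gene) had 4 with DESeq2's size factors, 47 without a filter, 2 under a stricter one, 398 with DESeq2, 32 with oocytes as libraries, 4 with limma on CPM, 8, 4 and 8 on the length-scaled table (pseudocount 1, 0.1 and rescaled), 5 without granulosa-rich libraries and 1 to 37 with 1 gilt left out. Gilt 205 (18 genes) had 303 without a filter, 5 under a stricter one, 879 with DESeq2, 3 with limma on CPM, 60, 97, 2 and 5 on the length-scaled table (pseudocount 1, 0.1, no filter and rescaled), 5 with sums of at least 2 oocytes, 3 without granulosa-rich libraries and 3 to 111 with 1 gilt left out. Gilt 801 (4 genes) had 2 with DESeq2's size factors, 80 without a filter, 1 under a stricter one, 274 with DESeq2, 37 with oocytes as libraries, 2 and 11 on the length-scaled table (pseudocount 1 and no filter), 1 with sums of at least 2 oocytes and 2 to 13 with 1 gilt left out. Gilt 803 (732 genes) had 1156 without a filter, 2492 with DESeq2, 1399 with oocytes as libraries, 353 with limma on CPM, 72, 93 and 47 on the length-scaled table (pseudocount 1, 0.1 and no filter), 5 without granulosa-rich libraries, which leaves 8 of its oocytes, and 120 to 799 with 1 gilt left out. The cause was not tested beyond the fewer samples or other genes each setting holds.

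Called lists numbered 0 with an estimated correlation for stage 5 against stage 1, the trend and gilt 803. Without granulosa-rich libraries they numbered 8, 14 and 6, and with 1 gilt left out 4 to 7, 4 to 9 and 11 to 11. With fry they numbered 0 for stage 5 against stage 1 and the trend. For gilt 803 fry ended the calls of oxidative phosphorylation (adjusted p = 0.141) and the spindle (0.0732). It added mRNA decay (0.0172) and insulin and mTOR signalling (0.0378). The other calls of gilt 803 held with fry, such as ribosomal proteins (0.00247) and oocyte genes (0.00427). In the trend the list of mitochondrial ribosomal proteins turned up without gilt 205 (adjusted p = 0.0472, and from 0.0472 to 0.534 with 1 gilt left out) and nuclear-encoded oxidative phosphorylation turned down without granulosa-rich libraries (0.000459). In gilt 803, the lists of the spindle (0.937), mitochondrial ribosomal proteins (0.000164), oxidative phosphorylation (8.06e-05), proteasome (0.288) and redox defence (0.937) turned direction without granulosa-rich libraries, as did CYP51A1 (-0.94), DHCR7 (-0.96), IDI1 (-0.0397), GADD45B (-1.48) and GADD45A (-1.60). The slope of the granulosa level was 0.127 with medians and -0.269 to 0.450 with 1 gilt left out, that of the mitochondrially encoded share -1.03 to 4.06, that of log10 totals 0.00415 to 0.133 and that of genes detected -506 to -51.3; the cause was not tested.

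Of the values of named genes under the alternatives, 1670 for stage 5 against stage 1 kept direction and side of the threshold, 103 changed sign without a call and 16 came past the threshold. In gilt 803, 706 kept both, 180 were no longer called and 17 came past the threshold; in gilt 205, 24 kept both and 36 were no longer called, and in gilt 801, 37 and 27. For C1QA and ZDBF2 together, 4 kept both and 19 were no longer called. Of the list values for stage 5 against stage 1, 188 kept both, 35 changed direction without a call, 17 came past the threshold and 19 were no longer called. For the trend these counts were 184, 29, 13 and 31, and 2 more turned direction with a call. For gilt 803 they were 167, 13, 4 and 18, and 5 more turned direction with a call. Lists that were never called count among those that kept both.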

Other observations

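All tests in this part were chosen only after the results were seen.

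Some abundant transcripts outside the lists varied widely between oocytes. RARRES1, a carboxypeptidase inhibitor, averaged 3254 CPM and ran from 15.79 to 27465, UBB, a polyubiquitin gene, averaged 1976 CPM, and RAB13, a small GTPase of vesicle traffic, averaged 1312 CPM and ran from 0 to 23623. ARRDC4, an arrestin-domain protein, averaged 1769 CPM and ran from 0 to 39227. Gilt 803, beside the changes above, had a higher PRKAR2B (2.92) and PRKAR1A (1.52), both regulatory subunits of protein kinase A, and a lower CDK1 (-2.28), the kinase partner of CCNB1.

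The 3 gilt 801 libraries with few markers of other cells and a low mitochondrially encoded share (stage 2 oocyte 4, stage 4 oocytes 2 and 3) had shares of 4.68, 4.73 and 3.62%. Their DNMT1 levels were 14519, 18379 and 15531 CPM, those of ZP3 7446, 3671 and 8472 CPM and those of BMP15 1942, 838 and 1945 CPM, and pairs of them correlated at r of 0.986 to 0.991. In stage 3 gilt 201, oocytes 3 and 4 had ZP3 at 65.4 and 119 CPM, GDF9 at 61.5 and 6.08 CPM, BMP15 at 305 and 264 CPM and DNMT1 at 3113 and 6616 CPM.

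ATP8, a subunit of ATP synthase encoded in mitochondria, and the unnamed gene ENSSSCG00000035520 differed between gilts 201 and 803 and gilts 205 and 801. Scaled to mitochondrially encoded counts, ENSSSCG00000035520 had a median of 48251 in gilt 201 and 43577 in gilt 803, against 58.6 in gilt 205 and 60.8 in gilt 801. For ATP8 the medians were 507 and 1275 against 13951 and 13548, with ranges that overlapped, since the highest oocyte of gilt 803 had 9103 and the lowest of gilt 801 had 8719. The mitochondrially encoded share of the libraries is argued against as the source for ENSSSCG00000035520, since the lowest oocyte of gilts 201 and 803 lay 62.8 times above the highest of the others. For ATP8 it is argued against too, since the lower median of gilts 205 and 801 was 10.6 times the higher median of the others and the oocytes did not overlap in the 52 deeper libraries. A candidate explanation is a variant of the mitochondrial genome against the reference, but 0 of the other 12 mitochondrially encoded members part the same gilts. A variant in a single gene would leave the other members alike, so the test leaves this open, and the position of the unnamed gene is not known here.

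Of 7055 genes of at least 10 CPM, ENSSSCG00000035520 was the 1 gene whose oocytes did not overlap between these pairs of gilts in all 55 libraries. ATP8 joined it in the 52 deeper libraries when scaled to mitochondrially encoded counts, and not by CPM. The other 2 ways of pairing the gilts gave 0 genes under both scalings and both sets of libraries. The share that chance gives was not computed, and oocytes of 1 gilt are not independent.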
